A study of Homo sapiens with 9 samples.

How the data were processed

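RNA was measured in 9 libraries of TC71 cells, a human Ewing sarcoma line, recovered from immunodeficient NSG mice. Per the series' design text, 100 cells in Matrigel were placed under the skin of the flank, and tumour cells were sorted by flow cytometry from lung, bone marrow and the primary tumour once tumours measured 1.5 cm across. The labels give 4 bone marrow libraries, 4 lung libraries and 1 primary tumour library. The libraries were made with a low-input template-switching kit, per the labels' protocols. The labels do not say which libraries came from the same mouse, so p-values measure the spread between these samples.

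The deposited table holds estimated counts per gene symbol, with fractions, not scaled to depth. Trim Galore, Salmon and the build hg38 are named in the submitters' processing notes, with no versions. A second deposited table gives, per library, the percent of reads assigned to each of 5 species, the fraction of reads in each counting category and the read length of 151 bases. How the authors made these percent and fraction values is not given in the sources used here. The count table has 34934 rows. Of these, 12 name reporter or drug-selection genes of vectors. They were kept out of the library sizes and tests of the other genes and took at most 0.0133% of a library's counts. Some rows carry dates in place of gene symbols in the deposited table and were left so. The strand setting of the counting is not given in the sources used here, and with a low-input kit a count near 0 can also come from molecules lost before sequencing. Every sample column of the tables was used.

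Estimated counts were rounded to whole numbers. Genes were filtered with edgeR's filterByExpr, leaving 17073, and scaled by TMM. All 9 libraries entered 1 edgeR 4.0.16 quasi-likelihood model with 3 groups, and genes were called at a two-sided Benjamini-Hochberg adjusted p below 0.05. Positive log2 fold changes mean higher in bone marrow, or higher in metastases than in the primary library. The primary tumour has 1 library. Its tests ask whether that library lies outside the spread of the metastasis libraries, assume that it varies as they do, and have no replicate check. CPM values are TMM-scaled and given as mean ± SD over 4 libraries. Those of vector genes are instead taken over all counts of a library, without TMM. Standard errors of the log2 fold change were derived from the edgeR test, as its absolute value over the square root of the F statistic.

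Gene lists were fixed before the data were examined, and 37 had at least 3 tested members. Each was tested with limma 3.58.1 camera on voom values, with a preset correlation of 0.01 and again with an estimated correlation, and with fry. Members were also adjusted over the list alone. For the primary library, the median of a list was placed among 10000 random lists of the same size matched on mean expression, as a description of these libraries.

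The rule for named genes was also fixed then. It allowed any measured gene of the polyamine lists and 9 ferroptosis genes whatever their result; up to 8 genes with the largest rise and 8 with the largest fall, and the 5 with the smallest p in each direction, among genes past the adjusted p with an average log2 CPM of at least 2 and no overlap between groups; and list members past the threshold, up to 4 per list. With none past it, the 5 smallest p in each direction are given as values. For the metastasis against primary comparison, values of polyamine genes were limited to ODC1, AMD1, SRM and SMS, and this limit was set after the values were seen. The condition on overlap for that comparison was that the primary library lay beyond all 8 others. Symbols in the form of clone or pseudogene names were not taken, a pattern that also holds some coding genes. Members that passed only when adjusted over the list alone, and genes outside the rule, are said to be so.

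The alternatives tried were median-ratio size factors, library size alone, no filter, a filter of at least 5 CPM in at least 4 libraries, DESeq2 1.42.0 on the same genes, limma voom with quality weights, a 2-fold threshold, the added condition that the primary library lie beyond all 8 others, the replicate number as a block, the 8 metastasis libraries alone, and each metastasis library left out in turn. The 4 others were chosen after seeing the data, among them a per-library offset for transcript length and GC content from GENCODE release 29. DESeq2 was given the same genes and group means as edgeR, and left 13868 genes with an adjusted p for bone marrow against lung. The 8 metastasis libraries were also split 4 against 4 in all 35 ways. The 9 libraries were compared pairwise and no 2 agreed within sampling noise (chi-square per degree of freedom at least 87.1 over 36 pairs).

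The edgeR step was tested on simulated data with the real means, dispersions and library sizes. For bone marrow against lung, over 16187 genes, it called 0% of genes changed 2-fold, 10.6% of those changed 4-fold, 28.6% at 8-fold and 41.7% at 16-fold, with 2 false calls. For metastases against the primary library, over 16185 genes, it called 0% at 2-fold, 2.08% at 4-fold, 10.6% at 8-fold and 27.1% at 16-fold, with 0 false calls. A floor of 3 counts over a group was used where a group had no counts, and it covers counting error only. Analyses were run in R 4.3.3 and Python 3.11.15.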

Results

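The transcriptomes of human TC71 Ewing sarcoma cells were compared between spontaneous metastases at 2 sites and the primary tumour in mice. Bone marrow and lung each had 4 libraries and the primary tumour had 1. Estimated counts summed to between 11550000 and 17910000 per library, to the nearest 10000. Bone marrow libraries held 15480000 ± 1680000 and lung libraries 12660000 ± 770000 (SD, n = 4 each), a difference with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 libraries can give, and an adjusted p of 0.114 over 20 library measures. On average 12.2 ± 1.91% of tested genes had no counts in lung libraries and 9.44 ± 1.99% in bone marrow libraries (exact permutation p = 0.0571). The biological coefficient of variation was 0.925, so single genes varied widely between libraries of a site.

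The comparison of bone marrow with lung asked how metastatic cells of the same line differ between sites. Of 17073 genes, 1 passed the edgeR test. XPO5, which exports microRNA precursors from the nucleus (chromosome 6, 43522330 to 43576075, hg38), was at 42.5 ± 18.4 CPM in bone marrow and 0.429 ± 0.225 CPM in lung (SD, n = 4 each), with a log2 fold change of 6.60 ± 0.63 (SE) and an edgeR adjusted p of 0.0440. The primary library held 22.7 CPM. The call was lost when any 1 of the 8 libraries was left out (edgeR adjusted p 0.0733 to 0.261), without both outlying libraries, bone marrow replicate 1 and lung replicate 3 (0.177), and with the replicate number as a block (0.570), while the log2 fold change stayed between 6.31 and 6.997 over single libraries left out. At an unadjusted p below 0.05 there were 1742 genes, 1080 higher in bone marrow and 662 higher in lung, against 854 expected by chance. DESeq2 called 468 genes, 300 higher in bone marrow and 168 higher in lung, and limma voom called 6. All 468 had the same sign and an unadjusted p below 0.05 in edgeR, which used the same counts, so this adds no separate support. Of the 468, the sites did not overlap for 350, and limma voom shared 6. Splits of the 8 metastasis libraries that mixed the sites gave 35 to 247 DESeq2 genes. The libraries of the sites did not overlap for 1002 genes, or 5.87% of those tested, where chance gives 2.86%.

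**Figure D1:**
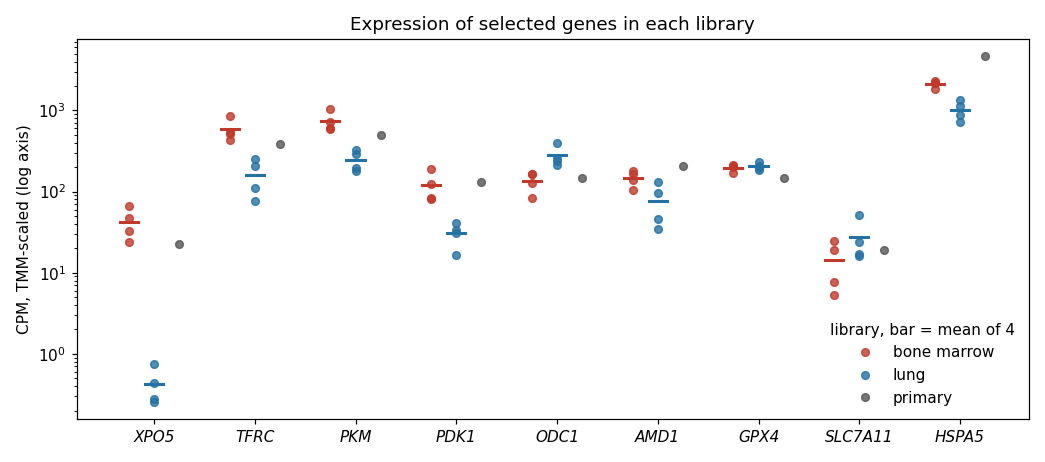
CPM of 9 genes in each library on a log axis, with points for single libraries and bars for the mean of 4 bone marrow or lung libraries. XPO5 lies at 42.5 CPM on average in bone marrow and 0.429 CPM in lung, whereas GPX4 lies at 198 and 205 CPM.

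With all libraries, hypoxia-inducible genes had the largest median difference of the 37 lists. Over single libraries left out their median ran from 0.76 to 0.99. That of mitochondrially encoded transcripts ran from -1.06 to -0.46, so the order can turn. Of 26 measured targets of the HIF transcription factors, 19 were higher in bone marrow, with a median log2 fold change of 0.82. The camera adjusted p was 3.9e-05 with the preset correlation, and the adjusted p was 0.115 with an estimated correlation. The fry adjusted p was 0.0461. Adjusted over the list alone, 5 members rose and none fell, and 0 passed over all genes in edgeR, while DESeq2 called 5. PDK1, a kinase that inhibits pyruvate dehydrogenase, was at 120 ± 50.8 CPM in bone marrow and 30.5 ± 10.1 CPM in lung. The mitophagy receptors BNIP3 and BNIP3L were at 320 ± 85.1 and 344 ± 29.2 CPM in bone marrow and at 104 ± 44.4 and 162 ± 50.3 CPM in lung. LOX, a collagen cross-linking enzyme, was at 15.0 ± 2.00 and 2.08 ± 2.44 CPM. The sites differed in library measures alongside this and the groups below: 78.6 ± 0.688% of reads were assigned to human in bone marrow and 75.3 ± 1.97% in lung, and 19.4 ± 0.652% and 22.2 ± 1.83% were unaligned (exact permutation p = 0.0286 each, adjusted p 0.114). Of 6 genes marking low RNA quality or nuclear RNA, 5 were lower in bone marrow (median -0.39, camera adjusted p 0.114, and adjusted p 0.410 with an estimated correlation).

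Glycolytic genes were also higher in bone marrow, in 14 of 17 cases, with a median log2 fold change of 0.61. The camera adjusted p was 4.3e-05, and the adjusted p was 0.410 with an estimated correlation. Adjusted over the list alone, 5 rose and 0 passed over all genes in edgeR, while DESeq2 called PKM (adjusted p 0.000392). Pyruvate kinase PKM was at 738 ± 206 CPM in bone marrow and 248 ± 73.3 CPM in lung, ENO1 at 2862 ± 1111 and 1392 ± 330 CPM, and GAPDH at 1071 ± 195 and 629 ± 130 CPM. Over the list, bone marrow replicate 1 had a mean log2(CPM + 1) of 6.37, close to the highest lung library (6.36), and the other bone marrow libraries 6.98 to 7.11.

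Mitotic genes were higher in bone marrow in 23 of 27 cases, with a median log2 fold change of 0.65. The camera adjusted p was 3.9e-05, and the adjusted p was 0.410 with an estimated correlation. TOP2A and the spindle factor TPX2 passed when adjusted over the list alone, 0 members passed over all genes in edgeR, and DESeq2 called TOP2A and TPX2 (adjusted p 0.00899 and 0.0130). Bone marrow replicate 1, at a mean log2(CPM + 1) of 6.06, lay within the lung range of 5.35 to 6.21, and the other bone marrow libraries were at 6.67 to 6.85. Cholesterol and fatty acid synthesis genes were higher in 21 of 27 cases, with a median of 0.58, a camera adjusted p of 0.0013 and an adjusted p of 0.410 with an estimated correlation. MSMO1 and MVK passed adjusted over the list alone, 0 members passed over all genes in edgeR, and DESeq2 called MSMO1 and MVK (adjusted p 0.0248 and 0.00208). Here too bone marrow replicate 1, at 5.13, lay within the lung range of 4.96 to 5.35, and the others were at 5.42 to 6.01.

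All 13 measured mitochondrially encoded transcripts were lower in bone marrow, with a median log2 fold change of -0.76. The camera adjusted p was 2.4e-08, and the adjusted p was 0.410 with an estimated correlation. No member passed on its own in edgeR, DESeq2 or limma voom. Reads from mitochondrial ribosomal RNA made up 0.158 ± 0.0560% of reads in bone marrow and 0.432 ± 0.0656% in lung (exact permutation p = 0.0286, adjusted p 0.114). The share of counts from mitochondrial genes varied within bone marrow, at 1.28%, 0.277%, 0.478% and 1.12% in replicates 1 to 4, and was 1.30 ± 0.147% in lung. Without bone marrow replicate 2 the median was -0.46. The sample table numbers the read file of that library far from the other 8, whose numbers run in sequence, with the same lane for all 9; the labels name no batch, and a batch of that library alone would hold 1 sample of 1 group, so no value within it can be given. Nuclear-encoded oxidative phosphorylation genes had a median of 0.04, with 22 of 43 higher in bone marrow.

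Immediate early and dissociation stress genes had a median log2 fold change of -0.48, with 15 of 25 lower in bone marrow. The camera adjusted p was 0.0107, and the adjusted p was 0.410 with an estimated correlation. Adjusted over the list alone, 4 fell and 1 rose, and 0 passed over all genes in edgeR, while DESeq2 called 4 lower in bone marrow. The transcription factors KLF6 and ATF3 were at 216 ± 38.6 and 95.4 ± 32.9 CPM in lung and at 110 ± 6.10 and 27.1 ± 15.2 CPM in bone marrow, whereas FOS was at 182 ± 94.7 CPM in lung and 437 ± 130 CPM in bone marrow. The camera call was lost without bone marrow replicate 3 (adjusted p 0.0975), without lung replicate 1 (0.0913) and with an offset for transcript length and GC (0.0789). The cells were sorted from different tissues, so for these genes tissue handling cannot be told apart from the site.

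**Figure D2:**
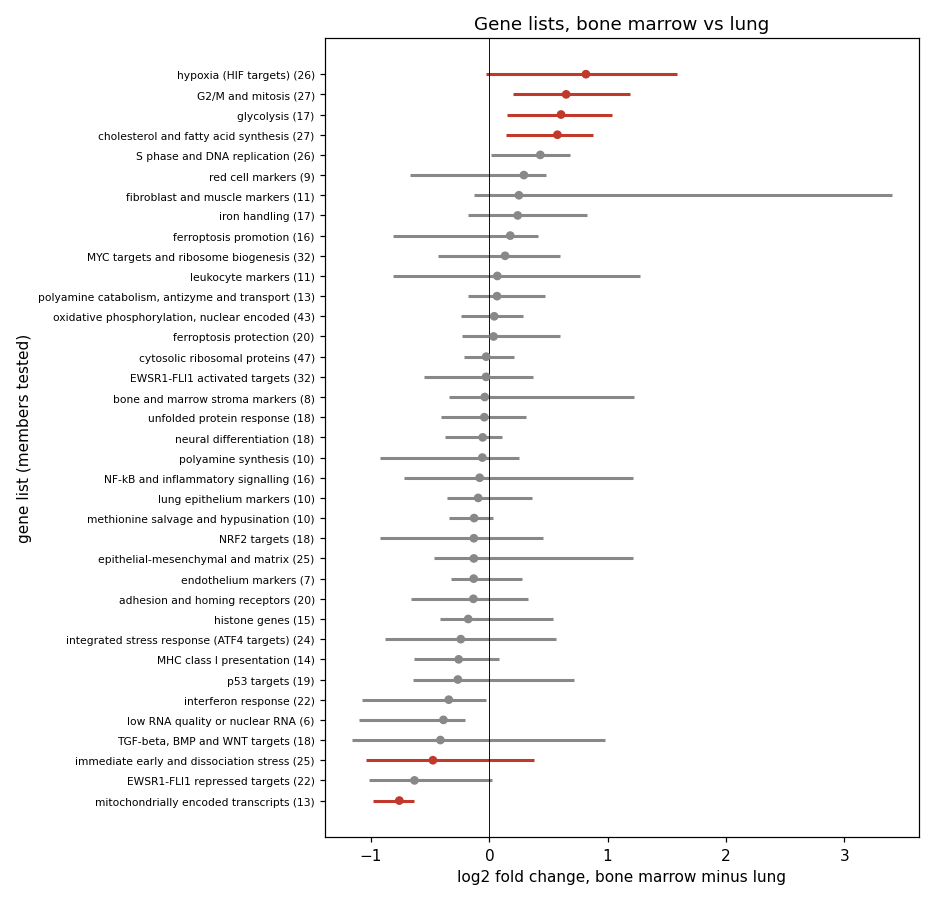
Median log2 fold change of each gene list between bone marrow and lung (points) with the lower and upper quartiles of its members (lines). Red marks the 6 lists with a camera adjusted p below 0.05 at the preset correlation, and none of them kept it with an estimated correlation.

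Polyamine genes were examined because the study's title concerns polyamine depletion. Ornithine decarboxylase ODC1, which makes putrescine (chromosome 2, 10439968 to 10448504, hg38), was at 279 ± 83.7 CPM in lung and 135 ± 38.1 CPM in bone marrow, with no overlap between sites. Its log2 fold change was -1.05 ± 0.30 (SE), with an edgeR adjusted p of 0.381 over all genes and 0.0640 adjusted over the list alone, so it passed neither, and a DESeq2 adjusted p of 0.0604. S-adenosylmethionine decarboxylase AMD1 was at 77.5 ± 45.2 CPM in lung and 146 ± 31.7 CPM in bone marrow (log2 fold change 0.91 ± 0.43, adjusted p 0.487). Spermidine synthase SRM was at 21.4 ± 10.2 and 21.5 ± 10.8 CPM, and spermine synthase SMS at 205 ± 45.7 and 187 ± 31.5 CPM, in lung and bone marrow. Of 10 measured synthesis genes, 5 were higher in bone marrow and 5 higher in lung, and 0 passed in edgeR, adjusted over the list alone or over all genes, or in DESeq2 or limma voom. Of 13 genes of catabolism, antizymes and transport, 7 were higher in bone marrow, and 0 passed either way in edgeR. The acetyltransferase SAT1 was at 59.9 ± 17.7 CPM in bone marrow and 54.1 ± 43.4 CPM in lung. SLC12A8 was detected in bone marrow at 3.14 ± 3.81 CPM and had no counts in lung, and DESeq2 called it (adjusted p 0.0345), while ARG1 had none in bone marrow.

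Ferroptosis is cell death through iron-dependent lipid peroxidation. GPX4, the enzyme that reduces lipid peroxides (chromosome 19, 1103926 to 1106791, hg38), was at 198 ± 20.9 CPM in bone marrow and 205 ± 20.4 CPM in lung, with a log2 fold change of -0.05 ± 0.18. The cystine transporter SLC7A11 was at 14.2 ± 9.15 and 27.2 ± 16.9 CPM, with a log2 fold change of -0.94 ± 0.63. Neither passed the test (edgeR adjusted p 0.951 and 0.612). The transferrin receptor TFRC was at 589 ± 189 CPM in bone marrow and 160 ± 80.4 CPM in lung. Its log2 fold change of 1.88 ± 0.40 passed adjusted over the list alone (0.0183) and not over all genes in edgeR (0.303), while DESeq2 called it (0.00248). The iron-sulfur scaffold ISCU was higher in lung, at 509 ± 40.7 against 337 ± 15.9 CPM, and also passed only within its list in edgeR, while DESeq2 called it (0.00654). Heme oxygenase HMOX1 was at 10.8 ± 10.2 CPM in lung and 0.586 ± 1.08 CPM in bone marrow (adjusted p 0.475). Of 20 protective genes 12 were higher in bone marrow, and of 16 promoting genes 9 were, with camera adjusted p of 0.859 and 0.739. Among the protective genes DESeq2 called TXNRD1 alone, higher in bone marrow (adjusted p 0.0136).

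Outside the rule, genes with no overlap between sites and an average log2 CPM of at least 2 were ranked by p within each direction. The first few of each direction after XPO5 were chosen after their values were seen. They were ZNF783, FAM200B, DPY19L4, IFT122 and ZNF146 in bone marrow. IFT122 had no counts in lung and was at least 187-fold higher in bone marrow against a floor of 3 counts over the group. In lung they were MCL1, SLC30A1, ZMYM6NB, RHOB, MIDN and ERRFI1. MCL1, which blocks apoptosis, was at 381 ± 122 CPM in lung and 77.4 ± 17.2 CPM in bone marrow (edgeR adjusted p 0.165, DESeq2 adjusted p 2.3e-09). With the filter of at least 5 CPM in at least 4 libraries, MCL1 and SLC30A1 passed as well.

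The metastases were next set against the primary tumour library. In edgeR, 0 of 17073 genes passed, and 817 had an unadjusted p below 0.05 where chance gives 854. DESeq2 called 97, of which 78 were higher and 19 lower in metastases. Limma voom called 48, of which 0 were higher and 48 lower, so the tools differed in direction. The median log2 fold change of all genes was 0.17, and the values below include that shift. The endoplasmic reticulum chaperone HSPA5 was at 4659 CPM in the primary library, against 2112 ± 202 CPM in bone marrow and 1021 ± 275 CPM in lung. ERRFI1, a feedback inhibitor of the EGF receptor, was at 594 CPM against 31.1 ± 4.78 and 171 ± 103 CPM. ZC3H13, TPR and TEKT2 were the other 3 lower in metastases among the smallest p. The mitochondrial ribosomal protein genes MRPL38 and MRPL49, and SIVA1, were higher in metastases; MRPL49 was at 57.5 CPM in the primary library against 296 ± 40.7 CPM in bone marrow and 189 ± 39.6 CPM in lung. TMEM120A and GALT had no counts in the primary library and were at least 71.2-fold and 31.0-fold higher in metastases against a floor of 3 counts. In edgeR none of these 10 passed, while DESeq2 called all 10 and limma voom the 5 lower in metastases.

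Nuclear-encoded oxidative phosphorylation genes were higher in metastases than in the primary library for 42 of 43 members, with a median log2 fold change of 0.39, above 99.7% of random lists matched on expression, a position that 9 red cell markers also reached. The camera adjusted p was 2e-07, and the adjusted p was 0.484 with an estimated correlation. Cytosolic ribosomal protein genes were higher for 38 of 47 (median 0.31, camera adjusted p 0.0048, and adjusted p 0.847 with an estimated correlation). Unfolded protein response genes were lower for 13 of 18 (median -0.41, camera adjusted p 0.0287, and adjusted p 0.484 with an estimated correlation). HSPA5 and HSP90B1 passed adjusted over the list alone. Genes repressed by the EWSR1-FLI1 fusion were lower for 14 of 22, and matrix and mesenchymal genes for 18 of 25, each with a camera adjusted p of 0.0184 and an adjusted p of 0.307 with an estimated correlation. No member of these 5 lists passed over all genes in edgeR, while DESeq2 and limma voom each called HSPA5 (adjusted p 0.00836 and 0.0276) and no other member. Genes that the fusion activates were lower as well, for 19 of 32 (median -0.24, camera adjusted p 0.596). Both fusion lists thus moved the same way. Alongside these, 5 of 9 red cell markers and 9 of 11 leukocyte markers were higher in metastases and 9 of 13 mitochondrially encoded transcripts lower (camera adjusted p 0.596, 0.535 and 0.399); the hemoglobin gene HBA1, chosen after its values were seen, was at 46.9 CPM on average in bone marrow (SD 29.03), 38.3 ± 61.9 CPM in lung and 3.53 CPM in the primary library. Without bone marrow replicate 1 the number of lists past the threshold fell from 5 to 1: the camera adjusted p became 0.122 for ribosomal protein genes (median 0.14) and 0.0578 for unfolded protein response, fusion-repressed and matrix genes. The unfolded protein response call was also lost without lung replicate 2 (0.0728), the ribosomal median was 0.19 without lung replicate 3, and with the offset for transcript length and GC the medians became 0.20 for oxidative phosphorylation (adjusted p 0.0031) and 0.10 for ribosomal protein genes (0.377), the latter being 0.11 (0.236) without bone marrow replicate 1 and lung replicate 3.

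**Figure D3:**
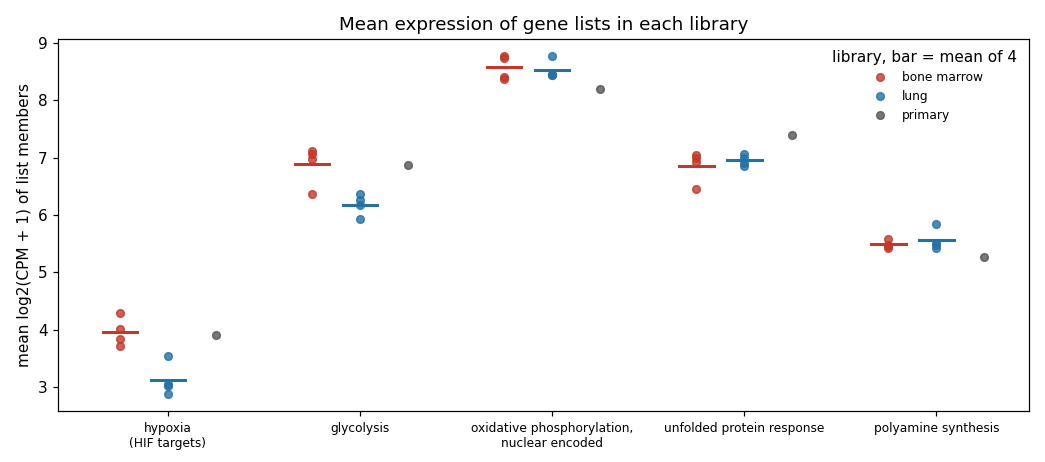
Mean log2(CPM + 1) over the members of 5 gene lists in each library, with bars for the mean of 4 bone marrow or lung libraries and a single point for the primary library. The primary library lies at 8.18 for oxidative phosphorylation genes, below the metastasis range of 8.37 to 8.77.

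Of the polyamine and ferroptosis genes, the primary library held 147 CPM of ODC1, 207 CPM of AMD1, 148 CPM of GPX4, 19.1 CPM of SLC7A11 and 389 CPM of TFRC, and in edgeR none of the 9 ferroptosis genes or of the polyamine genes passed. DESeq2 called OAZ2, an antizyme gene, higher in metastases and none of the other polyamine genes or the 9. AMD1 lay above and GPX4 below all 8 metastasis libraries. Of 10 measured polyamine synthesis genes, 8 were higher in metastases (median log2 fold change 0.36, camera adjusted p 0.215), so AMD1 went against most of its list. Of 13 genes of catabolism, antizymes and transport, 9 were higher (median 0.44, camera adjusted p 0.574). Neither list passed.

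Each site alone gave 0 genes against the primary library in edgeR. For lung 1100 genes had an unadjusted p below 0.05, DESeq2 called 165 and limma voom 4. For bone marrow 650 genes did, DESeq2 called 71 and limma voom 0, and without lung replicate 2 edgeR called 1. In lung, HSPA5 and HSP90B1, the hypoxia genes BNIP3, LOX and PDK1, and NOLC1 were lower than in the primary library adjusted over the list alone in edgeR. In bone marrow, SKIL was. DESeq2 called HSPA5, HSP90B1 and NOLC1 lower in lung, and of the hypoxia genes ADM alone, higher in lung and in bone marrow. Hypoxia genes were lower in lung than in the primary library for 16 of 26 (median -0.29, camera adjusted p 0.0139, and adjusted p 0.520 with an estimated correlation), with a median of -0.45, -0.14, -0.51 and -0.50 without lung replicates 1 to 4, and in bone marrow the median was 0.016 (camera adjusted p 0.906). Glycolytic genes were lower in lung for 11 of 17 (median -0.66, camera adjusted p 0.0162, and adjusted p 0.604 with an estimated correlation), and in bone marrow the median was 0.19 (camera adjusted p 0.707). The glycolysis call in lung was lost without lung replicate 2 (0.0532) or 4 (0.0529), and its median was -0.44 without bone marrow replicate 2 and -0.37 with the offset. Mitochondrially encoded transcripts were lower in bone marrow for 10 of 13 (median -0.74, camera adjusted p 0.00105, and adjusted p 0.655 with an estimated correlation; median -1.13 without bone marrow replicate 1), and in lung the median was -0.09 (camera adjusted p 0.627). Oxidative phosphorylation genes were higher than in the primary library in bone marrow (median 0.40, camera adjusted p 8.5e-07) and in lung (0.43, 5.5e-06), with medians of 0.25 in bone marrow without bone marrow replicate 1, 0.28 in lung without lung replicate 3, and 0.26 and 0.17 with the offset. Ribosomal protein genes were also higher in both (camera adjusted p 0.0253 and 0.00277), and unfolded protein response, fusion-repressed and matrix genes were lower in bone marrow (0.00772, 0.00191 and 0.0253). None of these calls held with an estimated correlation (adjusted p 0.219 to 0.871). The ribosomal call was lost in lung without lung replicate 3 (0.149) and with the offset (0.401), and in bone marrow without bone marrow replicate 1 (0.818) or 2 (0.0772), without lung replicate 1 (0.0633), with library size alone (0.179), with no filter or the stricter one (0.0585 and 0.0613), with the offset (0.702) and with limma voom (0.114). Without both outlying libraries it was lost in lung (0.103) and bone marrow (0.859); the matrix call was lost without bone marrow replicate 3 (0.0674). Whether the sites differ in their distance from the primary library was not tested beyond the direct comparison of bone marrow with lung.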

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

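The tests of vector genes in this part were chosen after their counts were seen. Within sites, 268 sets of 4 values were examined and 20 held a library far from the other 3, where chance gives about 13.4, so the number itself is little above chance. Bone marrow replicate 1 stood apart in 3 list means: S phase genes were at 5.22 (mean log2(CPM + 1); others 6.10 to 6.19), NF-kB and inflammatory genes at 3.32 (others 1.65 to 1.70) and histone genes at 6.69 (others 5.94 to 6.06). It was also low in FTL, at 1106 CPM against 2674 to 2925 CPM, and high in reads assigned to yeast, at 1.04% against 0.78% to 0.80%. Lung replicate 3 was high in oxidative phosphorylation genes, at 8.77 (others 8.43 to 8.45), in AIFM2, at 5.30 CPM (others 0.281 to 1.02), and in reads assigned to mouse, at 8.09% (others 7% to 7.18%). Lung replicate 1 was high in FTH1, at 2938 CPM (others 1882 to 2004), MIDN, at 113 CPM (others 86.1 to 89.1), SMOX, at 7.55 CPM (others 0 to 1.16), and ARG1, at 2.38 CPM (others 0 to 0.211).

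Single values that stood apart elsewhere were ERRFI1 at 23.9 CPM in bone marrow replicate 4 (others 32.9 to 33.9), SKIL at 309 CPM in bone marrow replicate 3 (others 168 to 189), HMOX1 at 2.20 CPM in bone marrow replicate 2 (others 0 to 0.148) and at 25.9 CPM in lung replicate 2 (others 4.39 to 7.99), and HSP90B1 at 267 CPM in lung replicate 4 (others 201 to 211). Among library measures, 0.000388% of reads in bone marrow replicate 4 were ribosomal and 0 in the other 3, 20.3% of reads in bone marrow replicate 3 were unaligned (others 18.9% to 19.2%), and the median correlation of bone marrow replicate 4 with the other libraries was 0.907 (others 0.897 to 0.899).

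The count table also holds vector genes that no comparison above uses. The fluorescent reporter tdTomato had 208, 138, 170 and 35 counts in bone marrow replicates 1 to 4, 19 and 12 in lung replicates 2 and 4, 1 in each of the other 2 lung libraries, and 159.9 in the primary library. That is 9.08 ± 5.36 CPM in bone marrow and 0.629 ± 0.666 CPM in lung (exact two-sided permutation p = 0.0286, the smallest possible; adjusted p 0.114 over 12 vector genes). Puromycin resistance had 932, 589, 493 and 147 counts in bone marrow, 229, 196, 322 and 620 in lung and 1470 in the primary library. Ampicillin resistance had 0, 4, 3 and 1 counts in bone marrow, 4, 6, 6 and 8 in lung and 4 in the primary library, and neomycin resistance had 1, 2, 3 and 2 in bone marrow, 4, 6, 11 and 8 in lung and 1 in the primary library. Of the other 8 vector genes, mCherry had 1.1 counts and chloramphenicol resistance 1 count in the primary library, and the rest had 0. Ampicillin and neomycin resistance were higher in lung in CPM, at 0.470 against 0.124 and 0.568 against 0.130 (exact permutation p = 0.0286 each, adjusted p 0.114), and puromycin resistance did not separate the sites (exact permutation p = 0.571). The labels do not describe a vector in these cells, and no explanation was tested.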

How the results depend on the processing

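The offset for transcript length and GC, robust empirical Bayes, leaving out 2 outlying libraries (bone marrow replicate 1 and lung replicate 3) and DESeq2 without the expression filter were chosen after seeing the data. Over 119 results and 2257 alternative values, 2003 kept their direction and side of the threshold or stayed within 1.5 times. Of the others, 96 passed the threshold only under the alternative, 44 of them with each form of DESeq2, 61 no longer passed it, 70 values of 20 results changed sign and 27 moved otherwise. A gene not called by edgeR counted as kept when it stayed uncalled with the same sign. Of 92 single-gene results edgeR called only XPO5, which kept its call in 10 of 20 alternatives. The number kept therefore says little about how firm the results are. DESeq2 has no test of lists, so it was not run for them. The cause of the changes below was not tested.

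For bone marrow against lung, the 1 gene called by edgeR became 3 with the filter of at least 5 CPM, 468 with DESeq2, 519 with DESeq2 without the filter, 6 with limma voom, 0 without the outlying libraries, and 0 whichever single library was left out. The labels do not say whether the replicate numbers pair the samples. Deviations of same-numbered libraries correlated at -0.0095, 0.037, -0.056 and -0.036, and only replicate 2 correlated best with its own number. These values show no shared deviation by number, and they cannot tell whether libraries came from the same mouse. With the replicate block the count was 0, on fewer residual degrees of freedom. At the depth of these libraries, 12.2 ± 1.91% of tested genes had no counts in a lung library on average, and where a whole group had none only a lower bound of a fold can be given. Metastases against the primary library moved from 0 to 97 with DESeq2, 116 with DESeq2 without the filter and 48 with limma voom; lung to 165, 191 and 4; bone marrow to 71 and 95 with both forms of DESeq2 and 0 to 1 over the libraries left out, the 1 arising without lung replicate 2. The 6 lists past camera for bone marrow against lung became 0 with an estimated correlation and 1 with fry. The 5 for metastases against the primary library became 0 with an estimated correlation and 1 to 5 over the libraries left out.

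The genes that changed sign were not called by edgeR, and their log2 fold changes in it ran from -1.58 for AIFM2 to 0.47 for OAZ3. In bone marrow against lung, log2 fold changes became: with library size alone, SRM -0.11, OAZ1 -0.019 and CAV1 -0.017; with the stricter filter, SRM -0.099, OAZ1 -0.030 and CAV1 -0.013; with the 8 metastasis libraries alone, SRM -0.016; with the replicate block, SRM -0.0098, SAT2 0.10, OAZ3 -0.055 and CAV1 -0.023; without the outlying libraries, SRM -0.15, ARG2 -0.063, SAT2 0.57, OAZ3 -0.29, SLC3A2 0.061, SLC18B1 0.17, CAV1 -0.16, FTL 0.033 and AIFM2 0.012; with limma voom, SRM -0.19, SAT2 0.34, OAZ3 -0.18, ATP13A2 0.16 and CAV1 -0.17; with the offset, CAV1 -0.087 and GPX4 0.090. Over the libraries left out in turn they ran, for SRM, from -0.26 to 0.26, SMS -0.24 to 0.024, SAT1 -0.18 to 0.83, SAT2 -0.50 to 0.49, SMOX -1.98 to 1.66, OAZ1 -0.026 to 0.21, OAZ3 -0.26 to 1.12, SLC3A2 -0.33 to 0.062, SLC18B1 -0.48 to 0.16, CAV1 -0.24 to 0.32, GPX4 -0.098 to 0.037, ACSL4 -0.17 to 0.78 and FTL -0.29 to 0.073. In metastases against the primary library they became, with library size alone, SRM -0.055 and SLC7A11 -0.055; with the offset, SRM -0.44; with limma voom, SRM -0.11, SMS 0.0056 and SLC7A11 -0.26; without the outlying libraries, SMS 0.047. Over the libraries left out they ran, for SRM, from -0.098 to 0.15, SMS -0.084 to 0.019, SLC7A11 -0.22 to 0.18 and CHAC1 -0.32 to 0.18.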

Other observations

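The tests in this part that were chosen after the result was seen are the comparison of mouse reads, the test of members above 50 CPM, the comparison of the primary library with the range of the metastasis libraries, the length and GC offset as an alternative, its margin of 1 bootstrap SD, and the enrichment among DESeq2 calls. Lists not described above, for bone marrow against lung, included interferon response genes, with 17 of 22 lower in bone marrow (median log2 fold change -0.34, camera adjusted p 0.500), and genes repressed by the EWSR1-FLI1 fusion, with 16 of 22 lower (median -0.63, camera adjusted p 0.114); neither passed. No list of markers of other cell types passed camera between the sites: of 11 leukocyte markers 6 were higher in bone marrow (camera adjusted p 0.944), and of 10 lung epithelium markers 6 were higher in lung (camera adjusted p 0.750). DESeq2 called single markers, CD68 (leukocytes) higher in lung at 7.98 ± 9.09 against 0.111 ± 0.222 CPM, and KRT8 (lung epithelium) at 25.5 ± 42.7 against 0.526 ± 0.260 CPM and COL1A2 (fibroblasts) at 1.93 ± 1.68 against 0.138 ± 0.0462 CPM higher in bone marrow, and edgeR called none of them (adjusted p 0.381, 0.414 and 0.370); they were chosen after their values were seen. Among genes that DESeq2 called higher in bone marrow, 5 of 24 hypoxia genes were present (Fisher's exact adjusted p 0.00514, background 13868 genes), and among those higher in lung 4 of 24 immediate early genes (adjusted p 0.00676). Fisher's test treats genes as independent and uses the same libraries, so it adds no separate support. Allowing for an estimated correlation, the camera adjusted p was 0.115 for hypoxia and 0.410 for immediate early genes.

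The 8 metastasis libraries can be split 4 against 4 in 35 ways. The real split gave the most genes by every measure run: 1 in edgeR, where the highest of the other splits gave 0, 468 in DESeq2 (highest other 247) and 1742 at an unadjusted p below 0.05 (highest other 1575). Each was reached by 1 split of 35, the smallest share that 35 splits can give. For the DESeq2 and unadjusted counts that share argues against chance without excluding it. The edgeR count of 1 decides nothing, because it rests on XPO5 alone, a call lost whichever library was left out. The 2 false calls of edgeR in simulated data came beside genes set to change, so they do not carry over to a lone call. Chance is not excluded for the number of lists either: 5 of 35 splits, the real one included, passed as many lists as the real 6. The other 4 each placed bone marrow replicate 1 with 3 lung libraries, passed 7 to 10 lists and gave 126 to 247 DESeq2 genes, which points to a structure among the samples in which that library lies apart from the other bone marrow libraries. By list, the camera p was as small in 5 of 35 splits for mitochondrially encoded transcripts (6.4e-10, smallest other 6e-12), 4 for mitosis (3.1e-06, other 2.6e-08), 3 for glycolysis (4.6e-06, other 2.3e-08), 5 for cholesterol and fatty acid synthesis (0.00017, other 1.6e-07) and 3 for immediate early genes (0.0017, other 0.00014), so chance is not excluded for these 5. For hypoxia genes the p was 3.1e-06 in the real split and 6.7e-05 in the next, with 1 of 35 splits as small. That is the smallest share 35 splits can give. It was the lowest among 6 lists put to this test, all past camera in the real split. Chance is therefore not excluded for hypoxia genes either. Their camera adjusted p was 0.115 with an estimated correlation.

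A first pattern is the higher level of hypoxia and glycolysis genes in bone marrow than in lung, with medians against the primary library of -0.29 and -0.66 in lung and 0.016 and 0.19 in bone marrow. A bias by transcript length or GC is argued against, since the medians after the offset were 0.77 and 0.57 (0.82 and 0.61 before). Loss of genes in lung libraries is argued against for abundant members only: the 17 with a mean above 50 CPM over all libraries had a median log2 fold change of 0.81 with a lower quartile of 0.60. That mean includes the bone marrow libraries, which can favour members higher there. The mouse share of reads was 0.168 percentage points higher in bone marrow (exact permutation p = 0.543), which decides nothing about reads from host cells. Left open, untested here, are the site itself, which may set these genes, and library quality. Unaligned reads (19.4% in bone marrow, 22.2% in lung) separated the sites. Chance is not excluded for hypoxia (1 of 35 splits, the smallest share possible) or for glycolysis (3 of 35 splits).

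A second pattern is the higher level of oxidative phosphorylation genes in metastases than in the primary library. The primary library's mean of 8.18 lay outside the metastasis range of 8.37 to 8.77, which decides nothing about the spread between libraries, because the two-sided exact rank p of 1 library among 9 cannot fall below 0.222. The offset for length and GC lowered the median log2 fold change from 0.39 to 0.20 (bootstrap SD 0.077), with a camera adjusted p of 0.0031 after it. Such a bias could account for part of the pattern, and the rest cannot be told apart from a difference of the tumour. The bound was 0.5 times the uncorrected median, and the corrected median lies within 1 bootstrap SD of it.

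The last pattern is genes near 0 in every lung library and present in every bone marrow library, like XPO5. With at most 1 CPM in every lung library and at least 5 CPM in every bone marrow library, 4 genes were of this kind and 1 of the reverse kind, a ratio of 4. Only 1 of 35 splits, the real one, gave as many (highest other 3). That is the smallest share 35 splits can give and rests on few genes, so random loss in single libraries is not decided. Lower complexity of the lung libraries may also contribute, and 5 genes are too few to decide it from that ratio of 4.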
